A study of Mus musculus with 60 samples.

How the data were processed

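Gene expression was measured on 60 Affymetrix mouse gene arrays, each hybridised with biotin-labelled cDNA from total RNA of R1 mouse embryonic stem cells. R1 is an established mouse embryonic stem cell line. It was grown on feeder cells, depleted of feeders before the experiment and exposed for 6 h in the undifferentiated state. The labels name 20 groups of 3 arrays: the solvent DMSO at 0.1%, 10 compounds called teratogens and 9 called non-teratogens. Per the labels, each compound was given at its IC10 (the concentration that lowers viability by 10%), at 1 mM or at its solubility limit, whichever was lowest. The descriptions cite an IC10 for 9 compounds and 1 mM for another 9, and give no basis for thalidomide.

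The deposited values are log2 signals, 1 per probe set and array, which the authors made with RMA, a method that summarises the probes of a set. The version and options of RMA are not given in the sources used here. The table holds 35556 probe sets with no missing values. The annotation lists 23410 of them, 21789 with a single gene symbol and 1621 with several, and has no entry for 12146. The 21789 probe sets with a single symbol, which stand for 19938 symbols, were tested. No genome build is named in the sources used here, so no positions are given. Array data have no read depth; the number of arrays, 3 per group, limits the precision. Values of the probe sets with several symbols or none were kept for an alternative.

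The deposited log2 values were used without further normalisation. All 60 arrays went into a single linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit and eBayes with default settings, 40 residual and 7.31 prior degrees of freedom). A contrast to DMSO was formed for each compound, and p-values were adjusted by Benjamini and Hochberg within each contrast. A probe set counts as called when its adjusted p is under 0.05. Log2 fold changes are given ± the SE of that model, with 3 arrays per group, and list means and medians are log2 fold changes against DMSO. Replicate numbers follow only the order of the deposited samples, so arrays were not paired. The labels call the arrays triplicates but do not say that they come from separate cultures. The p-values of a contrast between groups therefore measure the spread between these arrays. Tests on compound means measure the spread between compounds, and the list tests set the genes of a list against other genes.

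The classes were compared with the compound as the unit, because the class belongs to a compound: limma was fitted to 19 compound means, 10 against 9. The size of the response was compared with exact two-sided permutation tests of log10(calls + 1) and of the median absolute log2 fold change. For class prediction each compound was left out in turn and assigned to the nearer class mean over the 50 probe sets with the largest statistics among the other 18. Chlorthalidone was compared with hydrochlorothiazide by a contrast in the model of all arrays. Probe sets called in at least 10 compounds in the same direction were counted.

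Gene lists, 33 in all, were tested with cameraPR of limma on the moderated statistics, with 1 probe set per gene (the brightest). This test compares the members of a list with all other genes. Its direction is therefore relative to those genes and can differ from the sign of the list's mean against DMSO. The correlation between genes was preset at 0.01, and p-values were adjusted over all 627 pairs of a list and a compound. A further list, of mitochondrially encoded genes, had 1 measured member and was not tested. Each list was also tested with a correlation estimated from the residuals. The count of members called is given over all probe sets tested and adjusted over the list alone. The comparisons, the lists, the genes expected from the pharmacology of each compound, the rule for naming genes and most alternatives were fixed before the data were examined.

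The rule names, for each of the 4 compounds with most calls, the 14 probe sets that rose most and the 10 that fell most among those called with all 3 arrays beyond all 3 DMSO arrays. For the other compounds with calls it names the 5 that rose most and the 4 that fell most. It adds the pharmacology genes whatever their result and, for each list described, the 4 called members with the largest change, or the 2 largest members where none was called. For the classes it names the 5 smallest p-values in each direction, for probe sets shared by many compounds the leading 10, and for the diuretics the 5 largest differences in each direction. From these the text gives the leading ones and summarises the others.

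The alternatives were quantile normalisation of the deposited values, leaving out probe sets with a mean under the median, testing all probe sets of the table, a model of the 6 arrays of a compound and DMSO alone, eBayes with trend and robust settings, and the mean of the other 18 compounds as the reference. The letter b, which stands in the titles of 8 arrays without explanation, was used as a covariate or as a reason to leave those arrays out. For the lists, the mean of all probe sets of a gene was tried. For the classes, the 57 arrays were fitted with the compound as a random block, and the prediction used 20 or 200 probe sets. For the probe set calls of a contrast, each of its arrays was left out in turn, and for the classes each compound. For the lists against DMSO and the probe sets shared by many compounds, only the DMSO arrays were left out in turn. An adjustment for the interquartile range of each array, the removal of the 2 arrays farthest from their groups, the Fisher test of compounds without calls, the exact test of list means by class, the list tests between the diuretics and the choice of lists to describe were made after the data had been seen. The same holds for several tests of the closing section, which are named there.

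The procedure was tested first on simulated data. These took the mean and spread of each probe set from the real arrays and were drawn independently, without array-wide differences. Neither the shares of changed probe sets that were called nor the false calls therefore stand for those of the real arrays. Among 100 probe sets changed by 0.5 on the log2 scale in a group of 3 arrays, 93 were called, and all 100 were called at a change of 1, with 10 false calls. Between the classes, 51 of 100 were called at 0.2 and 96 of 100 at 0.4, with 11 false calls. Chance was also gauged by 100 draws in which the residuals of the 60 arrays were permuted, so that no group differed but all contrasts kept the shared DMSO arrays.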

Results

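RNA levels were measured in R1 mouse embryonic stem cells after 6 h with a compound or with the solvent, DMSO at 0.1%. The 60 arrays form 20 groups of 3: DMSO, 10 compounds that the labels class as teratogens (penicillamine, thalidomide, azacytidine, retinoic acid, dexamethasone, dimethadione, fluconazole, topiramate, methotrexate and valproic acid, VPA) and 9 that they class as non-teratogens (chlorthalidone, clozapine, glybenclamide, hydrochlorothiazide, loratadine, metoclopramide, ondansetron, paracetamol and sulfasalazine). The deposited log2 signals of an array had a median between 7.58 and 7.79. The median root mean square difference between 2 arrays was 0.133 within a group and 0.183 between groups, and no pair of arrays was identical. The interquartile range of an array lay near that of DMSO (3.20, 3.11 and 3.23 on its 3 arrays) in most groups, but it was lower on hydrochlorothiazide replicates 1 and 2 (2.97 and 2.99) and on dexamethasone replicate 3 (2.998).

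**Figure D1:**
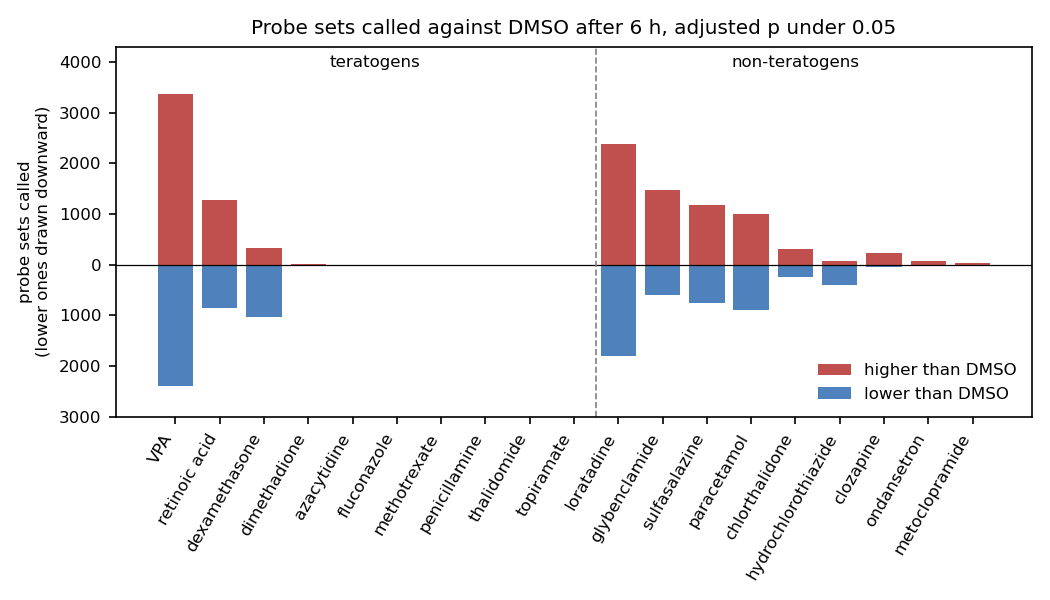
Probe sets called against DMSO for each compound (y axis, number of probe sets, higher ones above 0 and lower ones below), teratogens on the left and non-teratogens on the right. The tallest bars are those of VPA with 3374 higher and 2404 lower probe sets, and 6 teratogens have none.

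Each compound was compared with DMSO to see which genes it changed. Retinoic acid (0.024 mM) is a morphogen that acts through nuclear receptors. It changed 2140 of 21789 probe sets: 1285 rose and 855 fell, 45 of them by 2-fold or more. The largest rise was that of Cyp26a1 (probe set 10462853), the enzyme that degrades retinoic acid, from 6.64 ± 0.138 (SD, n = 3) in DMSO to 10.65 ± 0.058 (SD, n = 3), a log2 fold change of 4.004 ± 0.086 with an adjusted p of 7.47e-37. Its receptor gene Rarb rose by 1.77 ± 0.074, the retinal reductase gene Dhrs3 by 1.95 ± 0.073 and the germ cell gene Stra8 by 1.40 ± 0.096. Csn3 (2.31 ± 0.074), Slc15a1 (1.99 ± 0.082), Aqp3 (1.92 ± 0.077) and the homeobox gene Meis2 (1.94 ± 0.086) were among the 14 largest rises. The largest fall was that of Otx2 (probe set 10419356), a transcription factor of the epiblast and anterior neural plate, at -1.73 ± 0.078. The stem cell microRNA genes Mir302c (-1.33 ± 0.175), Mir302d (-1.15 ± 0.114), Mir302a (-1.13 ± 0.196) and Mir302b (-1.05 ± 0.152) fell with it, as did Foxd3 (-1.04 ± 0.076), Fgf5 (-1.01 ± 0.075) and Lef1 (-0.85 ± 0.060).

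Among lists fixed beforehand, the retinoic acid response list rose with retinoic acid (adjusted p = 6.15e-91, adjusted p = 2.77e-34 with an estimated correlation). Of its 21 measured genes 15 rose, none fell and 6 did not pass, and 16 rose when adjusted over the list alone. The Hox list, the genes that pattern the body axis, was called up at an adjusted p of 0.00728, but the adjusted p was 0.618 with an estimated correlation. In that list 7 of 37 genes rose and 1 fell, and 7 rose and 2 fell when adjusted over the list alone. The median of the list was -0.06 while its mean was 0.10, so the median and the test differ in sign. The rises were those of Hoxb1 (1.49 ± 0.080), Hoxa5 (1.47 ± 0.090), Hoxb4 (0.99 ± 0.080) and Hoxb2 (0.90 ± 0.082) and 3 others. The neural and ectoderm list fell (adjusted p = 2.45e-06, adjusted p = 0.0108 with an estimated correlation): 6 of 19 genes fell and 2 rose, or 8 and 2 when adjusted over the list alone. Otx2, Fgf5 and Neurod1 (-0.53 ± 0.077) fell, whereas Pax6 rose by 0.52 ± 0.077. The count of 2140 was 1313 without DMSO replicate 2, 1360 without retinoic acid replicate 2 and 876 in a model of the 6 arrays alone.

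VPA (1 mM) is an antiepileptic drug that inhibits histone deacetylases. It changed the most probe sets, 5778, of which 3374 rose and 2404 fell, 48 by 2-fold or more. The largest rises were those of the GTPase gene Rem2 (probe set 10415074, 1.59 ± 0.097, adjusted p = 7.59e-18), the glutamate transporter gene Slc1a1 (1.56 ± 0.066), Mindy2 (1.40 ± 0.101), Aqp11 (1.35 ± 0.092) and the immediate early gene Egr1 (1.33 ± 0.070). The histone gene H2ac1 rose by 1.16 ± 0.056, and 3 probe sets of Dennd4a rose. The largest falls were those of Cpsf4l (probe set 10392721, -1.44 ± 0.074, adjusted p = 1.36e-20), the neural plate gene Zic2 (-1.32 ± 0.064), Foxi3 (-1.25 ± 0.090), Foxd3 (-1.22 ± 0.076) and Bend3 (-1.21 ± 0.067). The pluripotency list fell (adjusted p = 1.88e-19, adjusted p = 0.000103 with an estimated correlation). It had 17 of 27 genes lower, 20 when adjusted over the list alone, and none higher. In it Gdf3 fell by 1.20 ± 0.054, Nr5a2 by 1.13 ± 0.065, Prdm14 by 0.77 ± 0.077 and Nanog by 0.68 ± 0.053. The neural and ectoderm list also fell (adjusted p = 1.12e-05, adjusted p = 0.0193 with an estimated correlation). It had 5 of 19 genes lower and 1 higher by either adjustment. Zic2, Fgf5 (-0.97 ± 0.075), Pax6 (-0.88 ± 0.077) and Otx2 (-0.80 ± 0.078) were among the 5.

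The list of genes known to respond to histone deacetylase inhibitors did not pass with VPA (adjusted p = 0.135), although 8 of its 20 genes rose and 2 fell, with the same counts adjusted over the list alone. Sv2a (0.67 ± 0.074), Syt11 (0.43 ± 0.077) and Apod (0.38 ± 0.083) rose and Crmp1 (-0.40 ± 0.070) fell. Hdac1 (0.08 ± 0.048, adjusted p = 0.249), Hdac2 (0.06 ± 0.069, adjusted p = 0.641) and Tubb3 (-0.12 ± 0.084, adjusted p = 0.339) were not called. Cdkn1a and the linker histone gene H1f0 were not analysed here. The immediate early list rose (adjusted p = 8.72e-06), but the adjusted p was 0.190 with an estimated correlation: 14 of 22 genes rose, or 15 with 1 lower when adjusted over the list alone. It held Egr1, Ier3 (0.59 ± 0.063), Zfp36 (0.56 ± 0.075) and Jun (0.45 ± 0.067). The lysosome and autophagy list was called up (adjusted p = 6.42e-07, adjusted p = 0.298 with an estimated correlation). It had 20 of 28 genes higher and 1 lower by either adjustment, among them Gabarapl1 (0.67 ± 0.070), Wipi1 (0.65 ± 0.084) and Uvrag (0.54 ± 0.062), while Rragd fell by 0.54 ± 0.067. The cholesterol biosynthesis list was called up (adjusted p = 0.00244, adjusted p = 0.538 with an estimated correlation). It had 12 of 21 genes higher and 1 lower, or 15 and 1 adjusted over the list alone. This call was lost with the mean of the other 18 compounds as reference (adjusted p = 0.626). The list held Tm7sf2 (0.52 ± 0.091), Pmvk (0.36 ± 0.075), Sc5d (0.36 ± 0.069) and Msmo1 (0.30 ± 0.072).

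Dexamethasone (0.1 mM) is a synthetic glucocorticoid. It changed 1361 probe sets, of which 329 rose and 1032 fell. The sterol synthesis genes Msmo1 (probe set 10578916, 0.84 ± 0.072, adjusted p = 8.54e-12) and Cyp51 (0.71 ± 0.082) and the cadherin gene Cdh6 (0.79 ± 0.090) rose most. The cytokine gene Il11 (probe set 10559667, -0.72 ± 0.068, adjusted p = 1.84e-10), the hyaluronan synthase gene Has2 (-0.67 ± 0.069) and Slc35d2 (-0.65 ± 0.102) fell most. Sterol genes moved as a group: the cholesterol biosynthesis list rose (adjusted p = 8.40e-48, adjusted p = 6.25e-08 with an estimated correlation). It had 14 of 21 genes higher, 17 adjusted over the list alone, none lower, and Nsdhl (0.62 ± 0.052) and Fdft1 (0.61 ± 0.049) next in size. Of the genes expected from the receptor, Tsc22d3, a glucocorticoid-induced leucine zipper gene, rose by 0.37 ± 0.082. Fkbp5 (0.06 ± 0.061, adjusted p = 0.6251), Per1 (0.11 ± 0.071, adjusted p = 0.364), Zbtb16 (0.06 ± 0.096, adjusted p = 0.733) and the receptor gene Nr3c1 (-0.14 ± 0.054, adjusted p = 0.111) were not called. The glucocorticoid response list did not pass (adjusted p = 0.0583), with 2 of 18 genes higher by either adjustment, Tsc22d3 and Sgk1 (0.18 ± 0.049). That list was called up with the interquartile range as a covariate (adjusted p = 0.00451), with the letter b as a covariate (adjusted p = 0.0120), with the 2 farthest arrays left out (adjusted p = 0.000766) and without DMSO replicate 1 or 3 (adjusted p of 0.0480 and 0.0185), so its miss depends on the setting.

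Also with dexamethasone, the list of endoplasmic reticulum chaperones fell (adjusted p = 0.000257, adjusted p = 0.298 with an estimated correlation). It had 6 of 20 genes lower and 10 adjusted over the list alone. Derl3 (-0.33 ± 0.090), Dnajb9 (-0.29 ± 0.090), Manf (-0.22 ± 0.049) and Pdia4 (-0.20 ± 0.052) led it. The list of BMP and Nodal targets fell (adjusted p = 2.23e-06, adjusted p = 0.161 with an estimated correlation). It had 5 of 16 genes lower, 8 adjusted over the list alone, led by the Nodal antagonist genes Lefty1 (-0.60 ± 0.089) and Lefty2 (-0.54 ± 0.086) and by Id3 (-0.46 ± 0.108) and Id2 (-0.26 ± 0.074). The dexamethasone count was 239 with the interquartile range of each array as a covariate, 1 in a model of the 6 arrays and 675 without replicate 3, the array farthest from its group. It was 2955 without dexamethasone replicate 2, 165 without DMSO replicate 3 and 549 without DMSO replicate 1. With the interquartile range as a covariate Derl3, Dnajb9, Manf, Pdia4, Id3 and Id2 were not called. The share of called probe sets that rose went from 24.2% to 39.4% under quantile normalisation and to 54.0% with the covariate (129 rose and 110 fell), so the balance towards falls depends on that choice.

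Dimethadione (1 mM) is the active metabolite of the antiepileptic drug trimethadione. It changed 26 probe sets, of which 22 rose and 4 fell. Cirbp, which encodes a cold-inducible RNA-binding protein (probe set 10364712, 0.41 ± 0.071, adjusted p = 0.0103), Bloc1s2 (0.39 ± 0.077), Bard1 (0.38 ± 0.077), Pmm2 (0.36 ± 0.070) and Stat4 (0.36 ± 0.081) rose most. Tmem38b (-0.68 ± 0.148), Cisd1 (-0.63 ± 0.140), the small RNA gene Rny3 (-0.61 ± 0.133) and DQ267102 (-0.41 ± 0.083) were the 4 that fell. Cacna1g (-0.03 ± 0.076, adjusted p = 0.932), Cacna1h (-0.14 ± 0.072, adjusted p = 0.501) and Hif1a (0.06 ± 0.050, adjusted p = 0.729) were not called. The count was 0 in a model of the 6 arrays or without dimethadione replicate 1, 9 without its replicate 2, 3 without DMSO replicate 1 and 1 without DMSO replicate 2.

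For the other 6 teratogens limma called 0 probe sets. The number at an unadjusted p under 0.05 was 1850 with penicillamine (1 mM), 1658 with thalidomide (0.35 mM), 1757 with azacytidine, 1463 with fluconazole (1 mM), 2575 with topiramate (1 mM) and 1435 with methotrexate (0.028 µM), out of 21789. Some 0 counts depended on the setting: azacytidine had 168 calls with the letter b of the titles as a covariate. Against the mean of the other 18 compounds there were 3 (fluconazole) to 3428 (topiramate). That mean holds responding compounds and so asks another question. Without 1 array the adjusted calls reached 24 with penicillamine (without its replicate 1), 30 with topiramate (without its replicate 2) and 11 with azacytidine (without its replicate 1). The azacytidine dose is 0.23 µM in the sample titles and 23 µM in their characteristics, and nothing in the data settles which holds. With penicillamine, a copper chelator, the metallothionein genes Mt1 (-0.24 ± 0.083, adjusted p = 0.437) and Mt2 (-0.23 ± 0.053, adjusted p = 0.301) and the transporter genes Slc30a1 (0.19 ± 0.068, adjusted p = 0.441) and Atp7a (0.21 ± 0.086, adjusted p = 0.502) were not called. The list of NRF2 targets, genes of the oxidative stress response, was called down with penicillamine (adjusted p = 2.08e-05, adjusted p = 0.0489 with an estimated correlation) although 0 of its 23 genes were called. Its mean was -0.04, while the median of all probe sets tested was 0.05 with penicillamine. Adjusted over the list alone 2 rose and 3 fell, and the members with the largest changes were Hmox1 (-0.31 ± 0.065, adjusted p = 0.284) and Taldo1 (0.22 ± 0.076, adjusted p = 0.424). A list of fibroblast markers, included because the cells had grown on feeders, was called up (adjusted p = 0.0487, adjusted p = 0.618 with an estimated correlation), with Pdgfrb (0.20 ± 0.063, adjusted p = 0.395) and Col1a1 (0.19 ± 0.083, adjusted p = 0.540) largest and 1 gene higher adjusted over the list alone. That call was lost without any of the 3 DMSO arrays (adjusted p of 0.128, 0.0511 and 0.0982).

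With thalidomide the NRF2 list was called up (adjusted p = 9.52e-09, adjusted p = 0.00319 with an estimated correlation). It had 0 of 23 genes called and 2 higher adjusted over the list alone. Its largest members were Cbr3 (0.32 ± 0.092, adjusted p = 0.519) and Nqo1 (0.29 ± 0.076, adjusted p = 0.443). The thalidomide target gene Crbn (0.06 ± 0.069, adjusted p = 0.870), Sall4 (-0.04 ± 0.042, adjusted p = 0.818), Ikzf1 (-0.16 ± 0.085, adjusted p = 0.668) and Fgf8 (-0.17 ± 0.085, adjusted p = 0.656) were not called. With azacytidine, which inhibits DNA methyltransferases, Dnmt1 (0.00 ± 0.054, adjusted p = 0.999), Dnmt3a (0.03 ± 0.057, adjusted p = 0.950), Dnmt3b (0.04 ± 0.049, adjusted p = 0.918) and Dazl (0.02 ± 0.081, adjusted p = 0.988) were not called. The list of germline genes repressed by methylation did not pass with azacytidine either (adjusted p = 0.659), with a median of 0.01 against a mean of -0.01 and a test pointing down, and 0 genes called by either adjustment. With methotrexate, a folate antagonist, Tyms (0.03 ± 0.055, adjusted p = 0.932) and Slc19a1 (0.00 ± 0.068, adjusted p = 0.992) were not called. The folate and purine list did not pass (adjusted p = 0.988) with 0 of 21 genes called by either adjustment. Its test pointed down while its median and mean were both 0.01. With topiramate Car2 (-0.09 ± 0.061, adjusted p = 0.545), Car4 (-0.08 ± 0.065, adjusted p = 0.602) and Gria1 (0.24 ± 0.098, adjusted p = 0.337) were not called.

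With fluconazole, an inhibitor of fungal sterol demethylase, Cyp51 (0.14 ± 0.082, adjusted p = 0.785), Hmgcs1 (0.04 ± 0.051, adjusted p = 0.932) and Sqle (0.06 ± 0.048, adjusted p = 0.856) were not called. The cholesterol biosynthesis list was called up (adjusted p = 9.83e-08, adjusted p = 0.219 with an estimated correlation). It had 0 of 21 genes called and 1 higher adjusted over the list alone. The amino acid response list, targets of the stress factor ATF4, was called up (adjusted p = 5.00e-12, adjusted p = 0.0111 with an estimated correlation). It had 0 of 28 genes called and 5 higher adjusted over the list alone. Nsdhl (0.25 ± 0.052, adjusted p = 0.0669) and Chac1 (0.40 ± 0.084, adjusted p = 0.0669) were the largest members of these lists. Against the mean of the other 18 compounds both lists pointed down with fluconazole (adjusted p of 0.00288 and 0.125).

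Loratadine (0.043 mM) is an antihistamine. It changed 4184 probe sets, the most among the non-teratogens: 2385 rose and 1799 fell. The largest rises were those of Ddit3 (probe set 10366881), a transcription factor of the stress response, at 1.58 ± 0.090 (adjusted p = 1.39e-18), of the glutathione-degrading enzyme gene Chac1 (1.55 ± 0.084), Wnk1 (1.46 ± 0.100), Rnf157 (1.27 ± 0.068) and Hspb6 (1.23 ± 0.070). The largest falls were those of Soga3 (-0.91 ± 0.080, adjusted p = 2.05e-12), the zinc transporter gene Slc39a10 (-0.81 ± 0.059), Enox1 (-0.79 ± 0.057) and Lefty1 (-0.77 ± 0.089). With loratadine the amino acid response list rose (adjusted p = 1.68e-47, adjusted p = 8.64e-11 with an estimated correlation). It had 24 of 28 genes higher, 25 adjusted over the list alone, and none lower, led by Ddit3, Chac1, Gpt2 (0.99 ± 0.065) and Trib3 (0.93 ± 0.068). Sterol synthesis genes moved together, and the cholesterol biosynthesis list rose (adjusted p = 4.54e-54, adjusted p = 5.21e-09 with an estimated correlation). It had 20 of 21 genes higher by either adjustment, led by Insig1 (1.19 ± 0.084), which retains the sterol sensor in the endoplasmic reticulum, Msmo1 (1.18 ± 0.072), Dhcr7 (0.96 ± 0.077) and Cyp51 (0.79 ± 0.082). Hmgcs1 rose by 0.55 ± 0.051, and Npc1 was not called (0.06 ± 0.059, adjusted p = 0.534). Lysosomal genes were also higher, and the lysosome and autophagy list rose (adjusted p = 1.38e-23, adjusted p = 0.00274 with an estimated correlation). It had 22 of 28 genes higher and 1 lower, or 24 and 1 adjusted over the list alone, led by the lysosomal genes Hexa (0.75 ± 0.079), Neu1 (0.70 ± 0.066), Lamp2 (0.64 ± 0.068) and Gla (0.63 ± 0.067). The count was 2723 without DMSO replicate 2.

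Clozapine (0.028 mM) is an antipsychotic. It changed 285 probe sets, of which 239 rose and 46 fell. The largest rises were those of the lipid genes Insig1 (probe set 10520362, 1.25 ± 0.084, adjusted p = 5.38e-15), Msmo1 (0.93 ± 0.072), Scd1 (0.91 ± 0.067), Cyp51 (0.90 ± 0.082) and Scd2 (0.81 ± 0.057). The falls were led by the non-coding RNA genes Rmrp (-1.02 ± 0.162) and Snora16a (-0.82 ± 0.158), with Tmem38b (-0.67 ± 0.148) and Cisd1 (-0.67 ± 0.140). Sterol synthesis genes moved together, and the cholesterol biosynthesis list rose (adjusted p = 1.47e-126, adjusted p = 2.02e-21 with an estimated correlation). It had 18 of 21 genes higher and 20 adjusted over the list alone, among them Lss (0.59 ± 0.071) and Hmgcs1 (0.50 ± 0.051). Lysosomal genes were also higher, and the lysosome and autophagy list rose (adjusted p = 3.63e-33, adjusted p = 0.000103 with an estimated correlation). It had 18 of 28 genes higher and 19 adjusted over the list alone, led by Hexa (0.65 ± 0.079), Gaa (0.42 ± 0.087), Fnip1 (0.38 ± 0.071) and Atp6v1c1 (0.31 ± 0.072). The amino acid response list was called up (adjusted p = 2.69e-08, adjusted p = 0.0669 with an estimated correlation). It had 3 of 28 genes higher, Chac1 (0.51 ± 0.084), Stc2 (0.32 ± 0.053) and Atf4 (0.26 ± 0.061), and 6 adjusted over the list alone. With clozapine it pointed down against the mean of the other 18 compounds (adjusted p = 0.201). Npc1 was not called (0.09 ± 0.059, adjusted p = 0.707). The count was 72 in a model of the 6 arrays, 174 and 140 without DMSO replicates 1 and 2, and 149 and 169 without clozapine replicates 1 and 3. The share of called probe sets that rose went from 83.9% to 70.0% under quantile normalisation and to 66.3% with the interquartile range as a covariate.

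Ondansetron (0.054 mM) is a serotonin receptor blocker against nausea. It changed 72 probe sets (63 rose, 9 fell), led by Chac1 (0.65 ± 0.084, adjusted p = 1.32e-05), Tmem167 (0.57 ± 0.116) and Ahnak2 (probe set 10402783, 0.53 ± 0.089). Olfr159 (-0.38 ± 0.092) and Unc5d (-0.35 ± 0.074) fell most. The cholesterol biosynthesis list rose (adjusted p = 2.03e-16, adjusted p = 0.0111 with an estimated correlation). It had 3 of 21 genes higher, Insig1 (0.43 ± 0.084), Msmo1 (0.35 ± 0.072) and Nsdhl (0.28 ± 0.052), and 14 adjusted over the list alone. With ondansetron the amino acid response list rose (adjusted p = 3.71e-14, adjusted p = 0.00403 with an estimated correlation). It had 6 of 28 genes higher and 14 adjusted over the list alone. The lysosome and autophagy list rose (adjusted p = 4.60e-16, adjusted p = 0.0249 with an estimated correlation). It had 3 of 28 genes higher, Fnip1 (0.39 ± 0.071), Lamp2 (0.28 ± 0.068) and Ctsl (0.26 ± 0.045), and 19 adjusted over the list alone. Htr3a (-0.19 ± 0.096, adjusted p = 0.361), which encodes the receptor that ondansetron blocks, Hmgcs1 (0.14 ± 0.051, adjusted p = 0.187) and Cyp1a1 (-0.07 ± 0.097, adjusted p = 0.778) were not called. Metoclopramide (0.17 mM) is a dopamine receptor blocker. It changed 43 probe sets (40 rose, 3 fell), led by the same probe set of Ahnak2 (0.56 ± 0.089, adjusted p = 0.000577), Insig1 (0.49 ± 0.084) and the lysosomal cystine transporter gene Ctns (0.46 ± 0.073). Cyth4 (-0.32 ± 0.074), Sall2 (-0.30 ± 0.068) and Trav19 (-0.28 ± 0.054) fell. The lysosome and autophagy list rose with metoclopramide (adjusted p = 4.05e-16, adjusted p = 0.0249 with an estimated correlation). It had 3 of 28 genes higher, Fnip1 (0.36 ± 0.071), Flcn (0.27 ± 0.064) and Ctsl (0.22 ± 0.045), and 15 adjusted over the list alone. Its cholesterol biosynthesis list was called up (adjusted p = 8.19e-10, adjusted p = 0.105 with an estimated correlation) with Insig1 as the 1 gene of 21 that rose and 4 adjusted over the list alone. With the mean of the other 18 compounds as reference this list pointed down with metoclopramide (adjusted p = 0.931), and the amino acid response list was not called with ondansetron (adjusted p = 0.120). Drd2 (-0.16 ± 0.096, adjusted p = 0.496), Htr3a (-0.15 ± 0.096, adjusted p = 0.532) and Hmgcs1 (0.10 ± 0.051, adjusted p = 0.391) were not called. Both counts fell to 0 in a model of the 6 arrays. With the interquartile range as a covariate they were 27 for ondansetron, where Insig1, Msmo1, Lamp2, Tmem167, Olfr159 and Unc5d were then not called, and 28 for metoclopramide, where Flcn and Cyth4 were not. Without 1 array they ranged from 11 (without ondansetron replicate 2) to 196 (without DMSO replicate 3) for ondansetron and from 7 (without DMSO replicate 2) to 75 (without DMSO replicate 3) for metoclopramide.

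Glybenclamide (0.37 mM) is a sulfonylurea that closes potassium channels. It changed 2079 probe sets, of which 1479 rose and 600 fell (944 and 758 with the interquartile range as a covariate). Gpcpd1 (probe set 10487945, 0.99 ± 0.075, adjusted p = 2.60e-13), Chac1 (0.93 ± 0.084), Hspb6 (0.92 ± 0.070), the amino acid transporter gene Slc43a2 (0.91 ± 0.075) and Gm13375 (0.87 ± 0.091) rose most. Lefty1 (-0.78 ± 0.089, adjusted p = 1.40e-08), Cyp2b23 (-0.77 ± 0.092), Tmem38b (-0.70 ± 0.148), the endothelin gene Edn1 (-0.67 ± 0.082) and the eye and neural gene Pax6 (-0.64 ± 0.077) fell most. With glybenclamide the amino acid response list rose (adjusted p = 2.92e-19, adjusted p = 0.000265 with an estimated correlation). It had 17 of 28 genes higher and 20 adjusted over the list alone, among them the transporter gene Slc7a1 (0.83 ± 0.083), Trib3 (0.50 ± 0.068) and Atf4 (0.42 ± 0.061). The NRF2 list rose (adjusted p = 2.82e-06, adjusted p = 0.0246 with an estimated correlation). It had 8 of 23 genes higher and 12 adjusted over the list alone, led by the heme oxygenase gene Hmox1 (0.61 ± 0.065) and Srxn1 (0.40 ± 0.058). The cholesterol biosynthesis list was called up (adjusted p = 3.73e-10, adjusted p = 0.0957 with an estimated correlation). It had 10 of 21 genes higher, 14 adjusted over the list alone, led by Insig1 (0.42 ± 0.084) and Nsdhl (0.38 ± 0.052). The channel genes Abcc8 (-0.21 ± 0.078, adjusted p = 0.0785), Kcnj11 (-0.24 ± 0.109, adjusted p = 0.164) and Abcc9 (-0.07 ± 0.078, adjusted p = 0.602) were not called. The count was 1210 in a model of the 6 arrays, 1126 without DMSO replicate 2, and 1246 and 1226 without glybenclamide replicates 1 and 3.

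Sulfasalazine (1 mM) is an anti-inflammatory drug that blocks cystine uptake. It changed 1940 probe sets, of which 1177 rose and 763 fell. Chac1 (1.37 ± 0.084, adjusted p = 8.25e-17), Hspb6 (0.86 ± 0.070), the amino acid transporter genes Slc1a4 (0.82 ± 0.066) and Slc6a9 (0.76 ± 0.081) and Mir302c (0.81 ± 0.175) rose most. Cyp2b23 (-0.70 ± 0.092), Fga (-0.53 ± 0.112), Olfr1510 (-0.52 ± 0.122) and Ddo (-0.51 ± 0.115) fell most. With sulfasalazine the amino acid response list rose (adjusted p = 7.80e-35, adjusted p = 6.39e-08 with an estimated correlation). It had 18 of 28 genes higher and 24 adjusted over the list alone, among them Gpt2 (0.75 ± 0.065), Trib3 (0.66 ± 0.068) and Slc7a1 (0.64 ± 0.083). The cystine transporter genes Slc7a11 (0.30 ± 0.090, adjusted p = 0.0293) and Slc3a2 (0.19 ± 0.036, adjusted p = 0.000397) rose, as did Nqo1 (0.24 ± 0.076, adjusted p = 0.0392). The list of germline genes repressed by methylation rose (adjusted p = 0.000789, adjusted p = 0.0456 with an estimated correlation). It had 5 of 27 genes higher and 9 adjusted over the list alone, among them the meiotic genes Sycp3 (0.50 ± 0.128), Mael (0.46 ± 0.097), Smc1b (0.43 ± 0.083) and Sycp1 (0.35 ± 0.090). With the interquartile range of each array as a covariate the count was 297, and Slc7a11, Nqo1, Mir302c, Fga, Olfr1510, Sycp3, Mael and Sycp1 were then not called. Without DMSO replicates 1, 2 and 3 it was 1057, 391 (335 rose and 56 fell) and 2994 (1435 rose and 1559 fell), so the balance of rises and falls depends on single DMSO arrays. Without dim probe sets 1203 rose and 247 fell. The count was 875 and 581 without sulfasalazine replicates 1 and 2 and 1133 in a model of the 6 arrays.

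Paracetamol (1 mM) changed 1909 probe sets, of which 1004 rose and 905 fell. The histone genes H2ac1 (probe set 10404127, -1.65 ± 0.056, adjusted p = 8.12e-28), H2ac4 (-1.25 ± 0.116) and H2bc3 (-1.05 ± 0.091) and the zinc finger gene Bnc2 (-0.93 ± 0.069) fell most. Scn3b (0.86 ± 0.075), Slc4a11 (0.84 ± 0.071), Pm20d1 (0.82 ± 0.087), Elovl2 (0.80 ± 0.084) and Ddit4l (0.79 ± 0.074) rose most. The list of replication-dependent histones fell (adjusted p = 5.63e-40, adjusted p = 1.50e-20 with an estimated correlation). It had 8 of 9 genes lower by either adjustment, among them the linker histone genes H1f5 (-0.91 ± 0.060) and H1f1 (-0.88 ± 0.066). The list of G2/M genes fell (adjusted p = 2.17e-28, adjusted p = 1.87e-06 with an estimated correlation). It had 17 of 22 lower and 19 adjusted over the list alone, led by Nusap1 (-0.56 ± 0.079), the mitotic kinase genes Aurka (-0.53 ± 0.053) and Plk1 (-0.48 ± 0.056) and Cenpf (-0.52 ± 0.083). The pluripotency list fell (adjusted p = 1.38e-23, adjusted p = 9.78e-06 with an estimated correlation). It had 17 of 27 lower and 19 adjusted over the list alone, led by Fbxo15 (-0.60 ± 0.073), Nr5a2 (-0.49 ± 0.065), Prdm14 (-0.48 ± 0.077) and Nr0b1 (-0.46 ± 0.059). The list of p53 targets rose (adjusted p = 1.29e-12, adjusted p = 0.0124 with an estimated correlation). It had 14 of 27 higher and 15 adjusted over the list alone, led by Ddit4l, Btg2 (0.70 ± 0.076), the apoptosome gene Apaf1 (0.48 ± 0.067) and Plk2 (0.39 ± 0.071). Hmox1 (0.40 ± 0.065, adjusted p = 1.62e-05) and Gclc (0.31 ± 0.088, adjusted p = 0.0153) rose, while Nqo1 (0.19 ± 0.076, adjusted p = 0.127) and Gclm (0.07 ± 0.064, adjusted p = 0.687) were not called. The count was 1166 without paracetamol replicate 2.

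Chlorthalidone (1 mM) is a diuretic. It changed 562 probe sets, of which 313 rose and 249 fell. Chac1 (probe set 10474972) rose most, from 9.10 ± 0.137 (SD, n = 3) in DMSO to 10.44 ± 0.067 (SD, n = 3), or by 1.34 ± 0.084 (adjusted p = 2.29e-16). It was followed by Adamts3 (probe set 10531195, 1.03 ± 0.136), Ahnak2 (probe set 10402783, 0.80 ± 0.089) and Hspb6 (0.70 ± 0.070). Nlrp9b (-0.92 ± 0.138), Lefty2 (-0.79 ± 0.086), Lefty1 (-0.75 ± 0.089) and Olfr307 (-0.63 ± 0.128) fell most. With chlorthalidone the amino acid response list rose (adjusted p = 5.66e-49, adjusted p = 4.34e-11 with an estimated correlation). It had 14 of 28 genes higher and 23 adjusted over the list alone, among them Trib3 (0.69 ± 0.068), Stc2 (0.67 ± 0.053) and Slc7a1 (0.63 ± 0.083). Also called was the lysosome and autophagy list, which rose (adjusted p = 8.91e-22, adjusted p = 0.00438 with an estimated correlation). It had 11 of 28 higher and 18 adjusted over the list alone, led by Hexa (0.57 ± 0.079) and Fnip1 (0.49 ± 0.071). The list of endoplasmic reticulum chaperones rose (adjusted p = 8.27e-09, adjusted p = 0.0384 with an estimated correlation). It had 4 of 20 higher, Herpud1 (0.60 ± 0.074), Derl3 (0.56 ± 0.090), Dnajc3 (0.28 ± 0.069) and Sdf2l1 (0.20 ± 0.058), and 6 adjusted over the list alone. The count was 194 in a model of the 6 arrays, 353 and 343 without DMSO replicates 1 and 3, and 319 and 361 without chlorthalidone replicates 2 and 3. It was 936 under quantile normalisation (601 rose and 335 fell). The excess of rises was not stable: 198 rose and 238 fell without DMSO replicate 2, 244 and 99 without DMSO replicate 3, and 352 and 667 against the mean of the other 18 compounds.

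Hydrochlorothiazide (1 mM) is another diuretic. It changed 473 probe sets, of which 66 rose and 407 fell. Cisd1, a mitochondrial iron-sulfur protein gene (probe set 10369885, -0.79 ± 0.140, adjusted p = 0.00533), Ccdc90b (-0.57 ± 0.087), Nlrp9b (-0.54 ± 0.138) and Fam136a (-0.54 ± 0.121) fell most. Entpd1 (0.41 ± 0.094), Fcer2a (0.41 ± 0.115) and Fam135b (0.40 ± 0.114) rose most. Car4, a carbonic anhydrase gene, fell by 0.37 ± 0.065 (adjusted p = 0.00533), while Slc12a3 (0.12 ± 0.098, adjusted p = 0.462), which encodes the thiazide-sensitive transporter, and Car2 (-0.11 ± 0.061, adjusted p = 0.278) were not called. The G1/S list was called down (adjusted p = 0.00915, adjusted p = 0.457 with an estimated correlation). It had 2 of 24 genes lower, Ccne2 (-0.44 ± 0.098) and Tyms (-0.21 ± 0.055), and 3 adjusted over the list alone. The narrow interquartile range of hydrochlorothiazide replicates 1 and 2 goes with these changes. The count was 2 with that range as a covariate, the G1/S list was then not called (adjusted p = 0.366), and Car4, Cisd1, Ccne2 and Tyms were then not called. It was 0 in a model of the 6 arrays, 0, 4 and 3428 (1209 rose and 2219 fell) without hydrochlorothiazide replicates 1, 2 and 3, and 180, 1367 (527 rose and 840 fell) and 5 without DMSO replicates 1, 2 and 3. Under quantile normalisation 105 rose and 367 fell, and against the mean of the other 18 compounds 4271 rose and 4237 fell, so the size of the excess of falls depends on the setting.

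Chlorthalidone and hydrochlorothiazide both carry a sulfonamide group, and hydrochlorothiazide has the benzothiadiazine ring system of the thiazides, which chlorthalidone lacks. Both were given at 1 mM for 6 h, and their contrast called 1161 probe sets, 974 higher and 187 lower with chlorthalidone. Chac1 (1.14 ± 0.084, adjusted p = 1.29e-13), Adamts3 (0.96 ± 0.136), Cisd1 (0.73 ± 0.140) and Serpinb6c (0.71 ± 0.086) were higher with chlorthalidone. The largest differences the other way were those of Zfp640 (-0.62 ± 0.161 and -0.50 ± 0.135 for 2 probe sets), Slc39a10 (-0.48 ± 0.059), Foxd3 (-0.48 ± 0.076) and Rbbp6 (-0.47 ± 0.110). The lysosome and autophagy list (mean difference 0.25, adjusted p = 1.46e-24, adjusted p = 0.000763 with an estimated correlation), the amino acid response list (0.25, adjusted p = 1.94e-20, adjusted p = 0.000118 with an estimated correlation) and the list of endoplasmic reticulum chaperones (0.20, adjusted p = 3.49e-13, adjusted p = 0.00153 with an estimated correlation) were higher with chlorthalidone. Car4 was higher with chlorthalidone by 0.28 ± 0.065 (95% interval 0.15 to 0.41, adjusted p = 0.00592). That call was lost with the interquartile range as a covariate (0.19 ± 0.064, adjusted p = 0.125) and without hydrochlorothiazide replicate 1 (0.20 ± 0.069, adjusted p = 0.154), and held without replicate 2 (adjusted p = 0.0275). The 3 lists stayed higher with the covariate, by 0.17, 0.22 and 0.16 (largest adjusted p of 1.42e-11), and without any single array of either compound. No difference was called for Slc12a3 (-0.02 ± 0.098, 95% interval -0.21 to 0.18, adjusted p = 0.936) or Car2 (-0.07 ± 0.061, 95% interval -0.19 to 0.06, adjusted p = 0.552), nor with the covariate, where that of Slc12a3 was 0.20 ± 0.072 (adjusted p = 0.159). Against DMSO the 2 diuretics shared 60 called probe sets, 5 higher and 55 lower in both, where independence would give 0.948 and 4.65. In 100 draws of permuted residuals the 2 shared 0.64 higher and 0.20 lower on average (highest 64 and 20), and part of the overlap may come from the shared DMSO arrays. The contrast count was 126 in a model of the 6 arrays and 401 with the interquartile range as a covariate (245 higher and 156 lower with chlorthalidone), where neither probe set of Zfp640 was called. It was 637 and 555 without chlorthalidone replicates 1 and 3 and 302, 434 and 2898 without hydrochlorothiazide replicates 1, 2 and 3.

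**Figure D2:**
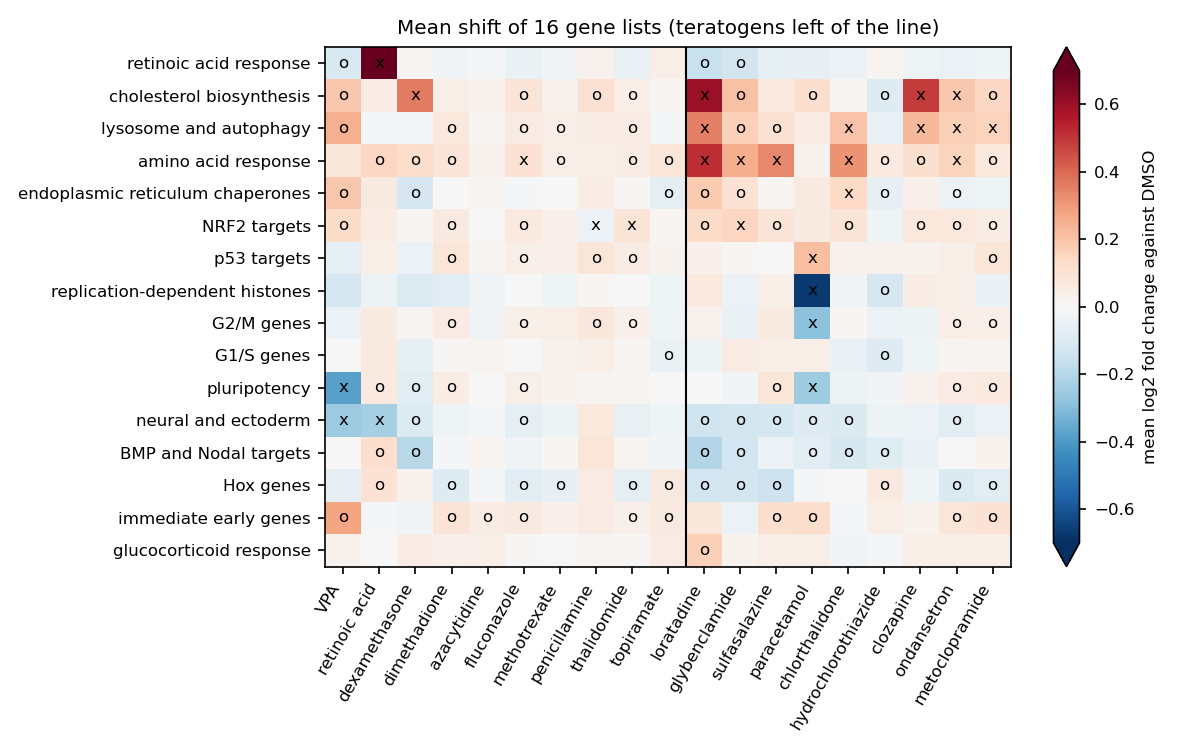
Mean log2 fold change against DMSO (colour) of the measured genes of 16 gene lists (y axis) in the 19 compounds (x axis, teratogens left of the line); an x marks a list called with the preset and the estimated correlation and an o a list called with the preset correlation alone. The cholesterol biosynthesis list is marked x in clozapine, loratadine, ondansetron and dexamethasone, and the colour scale ends short of the 0.83 of the retinoic acid response list with retinoic acid.

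Over all compounds, 177 of the 627 pairs of a list and a compound were called, 111 up and 66 down, and 28 of them with an estimated correlation. The amino acid response list was called up in 15 compounds, the lysosome and autophagy list in 12, the cholesterol biosynthesis list in 11 with 1 down, and the neural and ectoderm list was called down in 10. With the mean of the other 18 compounds in place of DMSO 110 pairs were called up and 99 down. In the order above the 4 lists were then up in 4, 7, 5 and 7 and down in 9, 9, 11 and 2. That mean holds the responding compounds, so a list that rises in most compounds points down against it in the weaker ones by construction, and these turns say nothing about the DMSO arrays. In 100 draws of permuted residuals the pairs called had a mean of 19.7 and a highest value of 118. The most probe sets called in any compound of a draw had a mean of 268.2 and a median of 0. Their 95th percentile was 1838 and their highest value 3058, although no group differed. Only the counts of VPA (5778) and loratadine (4184) lie above that highest value, so the size of a count alone does not exclude chance for the others. Probe sets changed by many compounds were asked for because all contrasts share the 3 DMSO arrays. In the same direction, 3 probe sets were called in at least 10 compounds, against 0 in each of the 100 draws. The draws cannot gauge this count, because at most 7 compounds had any call in a draw. They also leave out the effects of the compounds. Cirbp rose in 12 compounds (by 0.29 to 0.78), the zinc finger gene Sall2 fell in 11 (by -0.64 to -0.21) and the fucosidase gene Fuca2 rose in 10 (by 0.21 to 0.62). The glutamine synthetase gene Glul fell in 9, Chac1 and Cyb561a3 rose in 9, Klf12 rose in 9 and fell in 1, Usp10 fell in 9, and Lefty2 and Slc39a10 fell in 8.

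The classes were compared to ask whether teratogens and non-teratogens differ in expression. No probe set passed between the 10 teratogens and the 9 non-teratogens in limma on compound means (0 calls, smallest adjusted p of 0.976), with 955 at an unadjusted p under 0.05. Among the smallest p-values were those of Olfr1049 (difference 0.17 ± 0.038), Rsph4a (0.36 ± 0.090) and Olfr798 (0.17 ± 0.044), with higher means in teratogens. On the other side were 2 probe sets of Ahnak2 (-0.31 ± 0.069 and -0.45 ± 0.108), Gm128 (-0.33 ± 0.075) and the lysosomal genes Cln6 (-0.26 ± 0.061) and Mcoln1 (-0.20 ± 0.048), with higher means in non-teratogens. Each had an adjusted p of 0.976. Cln6 lay above DMSO in 9 of 10 teratogens and 9 of 9 non-teratogens. With the 57 arrays as units and the compound as a random block, 28 probe sets passed.

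Of the 33 lists, 16 were called between the classes with the preset correlation and 0 with an estimated one, and 0 passed an exact permutation test of list means (smallest adjusted p of 0.420). The lysosome and autophagy list had a mean of 0.05 in teratogens and 0.15 in non-teratogens (adjusted p = 2.97e-18, adjusted p = 0.124 with an estimated correlation, exact p = 0.0309). That of the amino acid response list was 0.08 and 0.21 (adjusted p = 4.68e-17, adjusted p = 0.124 with an estimated correlation, exact p = 0.0205). Prediction with each compound left out placed 14 of 19 compounds in their own class, 9 of 10 teratogens and 5 of 9 non-teratogens. The 5 placed wrongly were VPA, hydrochlorothiazide, metoclopramide, paracetamol and sulfasalazine.

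The size of the response was compared between classes and between dose bases. The mean log10(calls + 1) was 1.17 ± 1.62 (SD, n = 10) in teratogens and 2.77 ± 0.685 (SD, n = 9) in non-teratogens, a difference of -1.60 (exact two-sided permutation p = 0.0166, 0.0666 after adjustment over the 4 tests of this family). The median count was 0 in teratogens and 562 in non-teratogens, and 6 of 10 teratogens against 0 of 9 non-teratogens had 0 calls (Fisher's exact p = 0.0108, a test chosen after the counts were seen). The mean of the median absolute log2 fold change was 0.0722 ± 0.0162 (SD, n = 10) in teratogens and 0.0826 ± 0.0184 (SD, n = 9) in non-teratogens (exact permutation p = 0.204). Compounds given at an IC10 had 2.15 ± 1.40 (SD, n = 9) and those at 1 mM 1.91 ± 1.57 (SD, n = 9) for log10(calls + 1) (exact permutation p = 0.731). With the mean of the other 18 compounds as the reference the class difference was -0.302 (exact permutation p = 0.519), and with the interquartile range as a covariate it was -1.15 (exact permutation p = 0.0731).

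**Figure D3:**
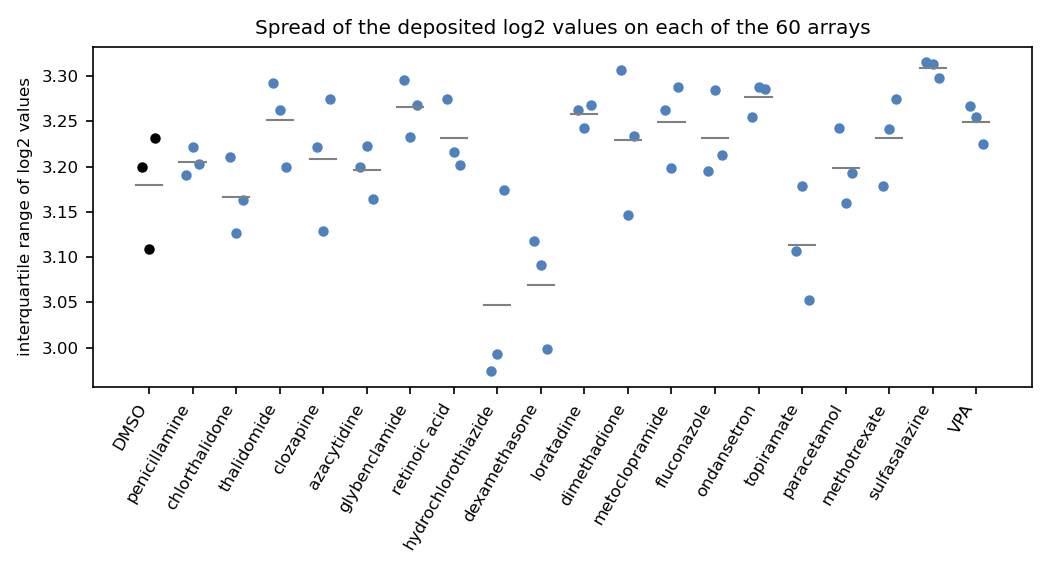
Interquartile range of the log2 values of each of the 60 arrays (y axis, log2 units) by group (x axis), with a line at each group mean and DMSO in black. Hydrochlorothiazide replicates 1 and 2 lie at 2.97 and 2.99 and dexamethasone replicate 3 at 2.998, under the 3 DMSO arrays at 3.20, 3.11 and 3.23.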

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

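The tests of array spread, of single arrays and of another reference for the hydrochlorothiazide, dexamethasone and list patterns were chosen after the results were seen; the counts over other splits of the samples and the draws of permuted residuals were planned before theirs. The measure of the spread test was also revised after its values were known. At first a ratio above 0.5 alone counted against the explanation, and a condition on the share of probe sets still called was added because so few were.

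Hydrochlorothiazide lowered 407 probe sets on arrays of which replicates 1 and 2 have the narrowest interquartile ranges of all 60. With that range as a covariate the median log2 fold change of the 407 went from -0.29 (quartiles -0.35 to -0.26, median SE 0.073) to -0.18 (quartiles -0.22 to -0.15, median SE 0.071), a ratio of 0.609, and 1 stayed called, because the fold shrank while the SE did not. The result meets neither the bound set for array spread as the cause nor the bound set against it, so array spread and an effect of hydrochlorothiazide cannot be told apart here, since replicate 3 (3.17) is its only array with a range inside that of DMSO (3.11 to 3.23), and a single array decides nothing. A few arrays may decide the count, and it follows the 2 narrow ones: the fewest calls without 1 of the 3 hydrochlorothiazide arrays were 0 (without replicate 1), with 4 without replicate 2 and 3428 without replicate 3. Of the 10 splits of the 6 arrays 2 gave as many calls as the real 473, and the other, hydrochlorothiazide replicates 1 and 2 with DMSO replicate 2 against the others, gave 3863. It puts the 3 narrowest of the 6 arrays on the same side, which points to a structure of these samples other than the treatment.

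Dexamethasone changed 1361 probe sets, and its replicate 3 lies farthest from its group of all arrays (root mean square deviation 0.178). The 675 calls without replicate 3 leave its role open: draws of permuted residuals reached 3058. With the interquartile range as a covariate the median absolute log2 fold change of the 1361 went from 0.27 (median SE 0.071) to 0.19 (median SE 0.069), a ratio of 0.723, and 177 stayed called, because the fold shrank while the SE did not. This too meets neither bound, so array spread and an effect of dexamethasone cannot be told apart for the calls as a whole. The same doubt holds for sulfasalazine, where the median absolute log2 fold change of its 1940 calls went from 0.28 (median SE 0.076) to 0.18 (median SE 0.075), a ratio of 0.634, and 239 stayed called. The rise of the cholesterol biosynthesis list kept an adjusted p of 1.93e-95 with that covariate, which argues against array spread as its cause, and an effect of dexamethasone on sterol genes stays a hypothesis. Of the 10 splits of the 6 arrays 2 gave as many calls as the real 1361, and dexamethasone replicates 1 and 2 with DMSO replicate 2 against the others gave 1639.

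The cholesterol biosynthesis and amino acid response lists rose in several compounds that share the 3 DMSO arrays as their reference. Against the mean of the other 18 compounds the cholesterol list stayed up in clozapine, loratadine and dexamethasone (largest adjusted p of the 3, 1.54e-18) and the amino acid list in chlorthalidone, loratadine, glybenclamide and sulfasalazine (largest adjusted p of the 4, 7.23e-09), which argues against chance values of the DMSO arrays as the cause in these. The call of the amino acid list in 15 compounds is another matter: in 9 of 100 draws of permuted residuals some list was called in the same direction in as many compounds (highest 19), so the number 15 may come from the shared DMSO arrays. Responses to the named compounds stay open as a hypothesis.

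With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave the most calls, 1 of 10, for chlorthalidone (562, highest other 1), clozapine (285, highest other 2), glybenclamide (2079, highest other 1), retinoic acid (2140, highest other 1), loratadine (4184, highest other 0), dimethadione (26, highest other 1), metoclopramide (43, highest other 0), ondansetron (72, highest other 1), paracetamol (1909, highest other 0), sulfasalazine (1940, highest other 0) and VPA (5778, highest other 0). All 10 splits gave at least the real 0 for penicillamine, azacytidine, fluconazole and methotrexate (highest other 0), thalidomide (highest other 2) and topiramate (highest other 55). Chlorthalidone against hydrochlorothiazide gave 1161 probe sets, the most of its 10 splits (highest other 170), and is listed here because the same contrast to DMSO differs between 2 related compounds. Over 100 splits of the 19 compounds into 10 and 9, 33 gave as many probe sets at an unadjusted p under 0.05 as the real 955 (median 611.5, highest other 5290) and 5 placed as many compounds right as the real 14 (highest other 16), so chance is not excluded for either. Of the 100 splits, the real one among them, 3 gave as many called lists as the real 16 (median 9, highest other 16). That share is under 0.05, but it was not adjusted for the other counts over these splits, so it does not exclude chance. With an estimated correlation 0 lists were called.

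Some compounds stood apart from the others of their class in the mean log2 fold change of a list, of which chance would single out about 1 in 20 of the 90 groups of values examined. Retinoic acid stood at 0.83 for the retinoic acid response list, with the nearest teratogen at 0.04. VPA stood at -0.38 for pluripotency, -0.25 for the Zscan4-type early embryo list, 0.12 for the list of responses to histone deacetylase inhibitors, 0.28 for immediate early genes and 0.25 for lysosome and autophagy. Dexamethasone stood at 0.36 for cholesterol biosynthesis, -0.10 for trophectoderm, -0.12 for FGF-ERK targets and -0.19 for BMP and Nodal targets. Paracetamol stood at 0.21 for p53 targets, -0.25 for pluripotency, -0.29 for G2/M genes and -0.67 for replication-dependent histones. Loratadine stood at 0.17 for the glucocorticoid response list, and penicillamine at 0.0797 for fibroblast markers. Among single probe sets, the mean level of Rsph4a was 8.35 with retinoic acid (nearest 7.95), that of Gpr12 was 6.62 with hydrochlorothiazide (nearest 6.47) and that of Ahnak2 (probe set 10402783) was 7.70 with VPA (nearest 8.02). Among the 13767 probe sets without a single gene symbol, which the comparisons do not use, 1126 were called with VPA, 1016 with loratadine, 513 with retinoic acid and 419 with glybenclamide.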

How the results depend on the processing

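The covariate for the interquartile range of each array and the removal of the 2 arrays farthest from their groups (dexamethasone replicate 3 and penicillamine replicate 2) were tests chosen after the data had been seen; the other alternatives were planned. Of 375 named gene results past the threshold, 227 stayed past it with the same sign under every alternative that could test them, as did 26 of 40 lists described and 7 of 10 genes named between the diuretics. For these lists, the fits without 1 array left out only DMSO arrays. Among results past the threshold no sign turned except against the mean of the other 18 compounds. Of 58 named gene results that were not called, 10 were called against that mean, 4 under quantile normalisation, 4 with the 2 farthest arrays left out, 2 without dim probe sets, 2 with the letter b as a covariate, 1 with the trend and robust settings and 3 in fits without 1 array. Among them were Hmox1 and Mt2 with penicillamine and Chac1 with fluconazole. The glucocorticoid response list with dexamethasone was called up under 5 alternatives. The 6-array models have fewer arrays to estimate the spread and lost 121 of the 375 gene calls, and leaving out 1 array leaves 2 against 3, with the spread taken from all groups. For each change given here without such a construction the cause was not tested. Signal over background cannot be had from the deposited values, so probe sets under the median of the means, left out in an alternative, were the only measure of low signal.

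Counts that moved by more than 1.5 times are given by alternative. In a model of the 6 arrays of a compound and DMSO there were 1 for penicillamine, 194 for chlorthalidone, 72 for clozapine, 1210 for glybenclamide, 876 for retinoic acid, 0 for hydrochlorothiazide, 1 for dexamethasone, 0 for dimethadione, 0 for metoclopramide, 0 for ondansetron, 1133 for sulfasalazine and 126 between the diuretics. Under quantile normalisation there were 2 for penicillamine, 936 for chlorthalidone and 35 for azacytidine. With the letter b as a covariate there were 2 for penicillamine, 3 for thalidomide, 168 for azacytidine, 47 for dimethadione, 92 for metoclopramide, 11 for fluconazole, 123 for ondansetron and 16 for topiramate. Without dim probe sets there were 2 for thalidomide, 28 for azacytidine, 775 for hydrochlorothiazide, 53 for dimethadione, 119 for metoclopramide, 5 for fluconazole, 169 for ondansetron and 19 for topiramate. With all probe sets of the table there were 2 for azacytidine. With the trend and robust settings there were 10 for azacytidine, 3 for fluconazole and 12 for topiramate. With the interquartile range as a covariate there were 855 for chlorthalidone, 42 for azacytidine, 2 for hydrochlorothiazide, 239 for dexamethasone, 28 for metoclopramide, 27 for ondansetron, 297 for sulfasalazine and 401 between the diuretics. With the 2 farthest arrays left out there were 1 for penicillamine, 1013 for chlorthalidone, 1 for thalidomide, 529 for clozapine, 45 for azacytidine, 3159 for glybenclamide, 1363 for hydrochlorothiazide, 129 for dimethadione, 207 for metoclopramide, 8 for fluconazole, 332 for ondansetron, 29 for topiramate and 3279 for sulfasalazine.

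Against the mean of the other 18 compounds, a contrast with more arrays behind its reference, there were 2503 for penicillamine, 1019 for chlorthalidone, 34 for thalidomide, 604 for azacytidine, 3816 for retinoic acid, 8508 for hydrochlorothiazide, 7466 for dexamethasone, 86 for dimethadione, 98 for metoclopramide, 3 for fluconazole, 33 for ondansetron, 3428 for topiramate, 3353 for paracetamol, 89 for methotrexate and 3031 for sulfasalazine. Not every count rose, since that of ondansetron was 72 against DMSO. Some of the largest belong to compounds with unusual arrays. Hydrochlorothiazide, dexamethasone and topiramate have arrays with a narrow interquartile range (3.05 on topiramate replicate 3). Penicillamine replicate 2 has a median of 7.786, against 7.637 and 7.636 on its other arrays. Whether these arrays cause the calls was not tested. The mean of the other 18 compounds holds the responding compounds, so probe sets and lists that move alike in many compounds turn sign in the weaker ones by construction. The sign turned for Cirbp in hydrochlorothiazide (-0.045), dexamethasone (-0.015) and paracetamol (-0.040), Sall2 in retinoic acid (0.047), Fuca2 in chlorthalidone (-0.035) and paracetamol (-0.037), Glul in paracetamol (0.0245), Cyb561a3 in retinoic acid (-0.10), metoclopramide (-0.0060) and paracetamol (-0.031), Chac1 in VPA (-0.22), and Slc39a10 in retinoic acid (0.059) and ondansetron (0.0078). Of the 15 compounds in which the amino acid response list was called up, it pointed down against that reference in 9 and was called down in 6 of them. Among the lists described compound by compound, those that turned down were amino acid response in clozapine (adjusted p = 0.201) and fluconazole (adjusted p = 0.125) and cholesterol biosynthesis in metoclopramide (adjusted p = 0.931) and fluconazole (adjusted p = 0.00288).

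The difference in log10(calls + 1) between the classes was -0.302 against the other 18 compounds and -1.15 with the interquartile range as a covariate, with an unadjusted exact p above 0.05, while the other alternatives gave -1.43 to -1.14 with an unadjusted p under it; the main difference itself had an adjusted p of 0.0666. Between the classes 28 probe sets were called with 57 arrays and the compound as a random block, against 0 in the other alternatives. The prediction was right for 14 compounds with 20 probe sets and for 15 with 200.

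The balance of rises and falls also turned for retinoic acid against the other 18 compounds (1878 rose, 1938 fell) and for paracetamol against them (1502 and 1851), with all probe sets of the table (936 and 993), with the interquartile range as a covariate (1159 and 1211), without DMSO replicate 2 (695 and 859) and without its replicate 1 (684 and 728).

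Leaving out 1 array at a time gave 0 to 24 calls for penicillamine, 319 to 436 for chlorthalidone, 0 to 1 for thalidomide, 140 to 217 for clozapine, 0 to 11 for azacytidine, 1126 to 2090 for glybenclamide, 1313 to 2591 for retinoic acid, 0 to 3428 for hydrochlorothiazide, 165 to 2955 for dexamethasone, 2723 to 4354 for loratadine, 0 to 21 for dimethadione, 7 to 75 for metoclopramide, 0 to 1 for fluconazole, 11 to 196 for ondansetron, 0 to 30 for topiramate, 1166 to 1554 for paracetamol, 0 for methotrexate, 391 to 2994 for sulfasalazine, 4923 to 5197 for VPA and 302 to 2898 between the diuretics. It gave 2 to 6 probe sets in at least 10 compounds (6 without DMSO replicate 3) and 155 to 185 list pairs, with only the DMSO arrays left out in turn for both. Leaving out a compound gave 0 probe sets between the classes. Shifts beyond 1.5 times not given elsewhere were those for metoclopramide (18 without DMSO replicate 1, and 16, 25 and 22 without its own replicates 1, 2 and 3), ondansetron (36 and 21 without DMSO replicates 1 and 2, 31 without its replicate 3), azacytidine (4 without DMSO replicate 2), penicillamine (1 without its replicate 2), thalidomide (1 without its replicate 1) and fluconazole (1 without DMSO replicate 1). The Hox list in retinoic acid was not called without DMSO replicate 3 (adjusted p = 0.0688).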

Other observations

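The choice of the lists and overlaps described here and the tests of both hypotheses were made after the results were seen.

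With chlorthalidone the mesendoderm and primitive streak list was called down (adjusted p = 5.76e-05, adjusted p = 0.0896 with an estimated correlation), with 3 of 17 genes lower: Lefty2 (-0.79 ± 0.086), Eomes (-0.44 ± 0.067) and Wnt8a (-0.26 ± 0.072). With dexamethasone the list of FGF-ERK targets was called down (adjusted p = 0.00213, adjusted p = 0.457 with an estimated correlation), with 4 of 14 genes lower, the feedback inhibitor genes Spry4 (-0.32 ± 0.072), Spred1 (-0.22 ± 0.059), Dusp6 (-0.20 ± 0.058) and Spry2 (-0.18 ± 0.057). With loratadine the glucocorticoid response list was called up (adjusted p = 0.00123, adjusted p = 0.219 with an estimated correlation), with 9 of 18 genes higher and 1 lower, led by the metallothionein gene Mt1 (0.81 ± 0.083) and Ddit4 (0.79 ± 0.091), both of which other stresses also induce.

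The called probe sets of some compounds overlapped more than independent draws would give. Loratadine and glybenclamide shared 997 higher and 327 lower probe sets (161.9 and 49.5 under independence), and loratadine and sulfasalazine shared 860 and 274 (128.8 and 63.0). Paracetamol and VPA shared 661 and 549 (155.5 and 99.9). All contrasts share the DMSO arrays, which raises such overlaps by itself. In 100 draws of permuted residuals loratadine and glybenclamide shared at most 0 higher and 1 lower, loratadine and sulfasalazine 0 and 0, and paracetamol and VPA a mean of 1.36 and 0.22, each from a single draw. The draws leave out the effects and independence leaves out the shared arrays, so the excess over either is not a measure of a shared effect, and part of it may come from the shared arrays. The DMSO arrays were not split between the compounds of a pair.

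A hypothesis for paracetamol is that fewer cells had passed S phase, which may lower histone and G2/M genes while G1/S genes are kept. Its test asked that the G1/S list not be called down in the same arrays. That list had an adjusted p of 0.229 and pointed up, with 5 of 24 genes higher and 0 lower. The hypothesis stays open, since cell cycle phase was not measured and a p that misses the threshold does not show that the list did not change.

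A hypothesis for clozapine, loratadine, metoclopramide and ondansetron is that they may share a rise of cholesterol biosynthesis and lysosome genes. The mean of the cholesterol list was 0.36 in the 4 and 0.09 in the other 15 compounds (exact permutation p = 0.00516, 0.0851 after adjustment over the 33 lists). For the lysosome and autophagy list it was 0.22 and 0.07 (exact permutation p = 0.00464, 0.0851 after adjustment). The 4 were grouped after their lists had been seen, so these p-values overstate the evidence, and neither passes the adjustment.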
